A study of Citrus maxima and Citrus sinensis with 8 samples.

How the data were processed

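Leaf RNA of seedlings of 2 citrus species, Citrus grandis (pummelo, whose organism label uses the synonym Citrus maxima) and Citrus sinensis (sweet orange), was sequenced on an Illumina HiSeq 2000. Per the labels, seedlings were grown with aluminium for 18 weeks or as controls, and equal amounts of leaves from 5 seedlings, each in its own pot, were pooled into 1 biological replicate. Each of the 4 groups had 2 such replicates, which gave 8 libraries from independent extractions of total RNA.

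The authors deposited 4 tables of FPKM, 1 per group with a column for each library, per the file headers. FPKM is the number of fragments on a gene scaled by the length of the gene and by the total of the library. The submitters' processing notes name Bowtie, TopHat2, HTSeq and edgeR 1.18.0 without saying what each was used for. The genome build and annotation are not given in the sources used here. Both species were listed on the same 30297 gene IDs in the same order. Of these, 23393 carry IDs of 9 numbered series (Cs1g to Cs9g), 6013 begin with orange1.1t and 891 have another prefix. Reads of both species were therefore counted on 1 gene set, and a gene that differs in sequence between the species can lose reads in either of them. The files do not pair the IDs with gene names or descriptions, and no annotation was used here. For that reason the 47 gene lists fixed before the data were examined could not be matched to any gene, and no list was tested.

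The files hold no read counts, but FPKM printed to many digits is a whole number of reads divided by a gene length and a library total. Whole reads, gene lengths and library totals were recovered from the ratios between libraries and between genes. Of the 23370 IDs above 0 in any library, 22312 were above 0 in several libraries and 1058 in 1 library, while 6927 were at 0 in all 8. For the IDs above 0 in several libraries, all recovered values (100%) lay within 0.01 of a whole number. The recovery searches for whole numbers, so this check is weak by itself. The totals behind the FPKM ranged from 16443205 to 19794247 reads, a ratio of 1.2, and at least 99.93% of each total was recovered on genes. On simulated libraries, every read of 99.73% of 22366 genes and all 8 totals came back as simulated. Recovered reads served for counting error, lower bounds and 1 alternative test. At the median length of 1620 bp, 3 reads correspond to between 0.0936 and 0.113 FPKM. Intervals and bounds made from reads cover counting error only, since reads copied by PCR are not independent molecules.

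Differences were tested with limma 3.58.1 in R 4.3.3 on log2(FPKM + 1), with no further scaling of the deposited FPKM. Genes with a mean FPKM of at least 1 over the 8 libraries were kept, which left 16327. A mean per group was fitted to all 8 libraries, so that all 4 groups shared 1 estimate of the spread per gene with 4 residual degrees of freedom, moderated with a trend on expression. P-values were two-sided and adjusted over genes by the Benjamini-Hochberg method, and a gene was called at an adjusted p below 0.05. Fold changes are on the log2(FPKM + 1) scale, which understates the change of genes at low FPKM. The comparisons were aluminium against control in each species, the difference of these effects between species, and C. grandis against C. sinensis in control and in aluminium leaves. The labels describe the replicates as separate pools of seedlings. Replicate numbers were not used to pair libraries.

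Without gene names, the rule fixed before the data were examined allowed at most 2 IDs that rose and 2 that fell per comparison. These were the called genes with the largest log2 changes among those with a mean of at least 5 FPKM in the higher group and both libraries of 1 group above both of the other. For the difference between species, the effects in all pairs of libraries had to be separated in the same way, and for the species the rule was applied in control leaves. Overlaps of calls were set against the product of the list sizes over the genes tested. Because the comparisons share 1 spread per gene, they were also set against that product summed over 50 bins of genes ranked by the spread, a check added after seeing the data. The Fisher's exact test planned for the overlaps assumes lists that are independent and is not reported.

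The test was run on simulated data before use. Of 100 genes changed 2-fold among 16321, 85% were called between libraries simulated as C. sinensis and 90% between those simulated as C. grandis. Of 100 genes changed 1.5-fold, 14% and 24% were called. False calls made up 3.9% and 8.8% of the calls in these comparisons. All simulated groups shared 1 spread, and no difference between species was simulated. The real pairs of replicates had spreads beyond counting error of 0.023 to 0.246 on the log2 scale. These rates may therefore not hold for the real libraries.

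The agreement of each pair of replicates was measured on recovered reads with a chi-square per gene, over genes with at least 20 reads in the pair. The mean chi-square, which is near 1 when a pair differs by counting error alone, was 1.77 for C. grandis aluminium, 9.69 for C. sinensis control, 58.9 for C. grandis control and 82.7 for C. sinensis aluminium. The C. grandis aluminium pair thus differed by somewhat more than counting error alone would give. It was kept as 2 replicates, as labelled, and was also tried as 1 replicate. Other alternatives changed the pseudocount to 0.1 or 5, the filter to none or to 5 FPKM, and the scaling to libraries centred on their median or to quantile normalization. Further ones changed the prior, added the replicate number as a block, used only the libraries compared, added a fold minimum of 1.5, left out each library in turn, or applied limma-voom to the recovered reads. The last of these and the joining of the C. grandis aluminium libraries were chosen after seeing the data. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for the rest.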

Results

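The libraries measured leaf mRNA of C. grandis and C. sinensis seedlings after 18 weeks with aluminium or as controls, with 2 replicates per group, each a pool of 5 seedlings. Aluminium becomes soluble in acid soils and is toxic to plants, and the study set side by side 2 citrus species that differ in how well they tolerate it. In published work on these species, C. sinensis is regarded as the more tolerant. The library totals behind the FPKM were 16443205 and 18755844 reads for C. grandis control and 17364864 and 16686351 reads for C. grandis aluminium. They were 19794247 and 19670766 reads for C. sinensis control and 16926806 and 19296323 reads for C. sinensis aluminium. Between 15509 and 16051 genes reached 1 FPKM in each library. The 10 most abundant genes took 8.1% and 8.3% of the reads in the C. sinensis control libraries, 6.1% and 7.3% in the C. sinensis aluminium libraries, and 4.3% to 4.5% in the 4 libraries of C. grandis. The median log2(FPKM + 1) over the genes tested was 3.55 in both C. sinensis control libraries, 3.70 and 3.68 in C. sinensis aluminium, 3.73 in both C. grandis control libraries and 3.68 in both C. grandis aluminium libraries.

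The first principal component held 65.2% of the variance and separated the species, and the second held 20.4% and ran from control to aluminium leaves in both. The aluminium libraries of C. sinensis lay apart on the second component, at -52.63 for replicate 1 and -3.48 for replicate 2. The C. grandis aluminium libraries lay at -35.58 and -35.72, the C. sinensis control libraries at 17.3 and 16.87, and the C. grandis control libraries at 47.58 and 45.67. Replicates of C. grandis aluminium differed least, with a spread beyond counting error of 0.023 on the log2 scale over genes with at least 1000 reads. That spread was 0.095 for C. sinensis control, 0.19 for C. sinensis aluminium and 0.246 for C. grandis control.

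**Figure D1:**
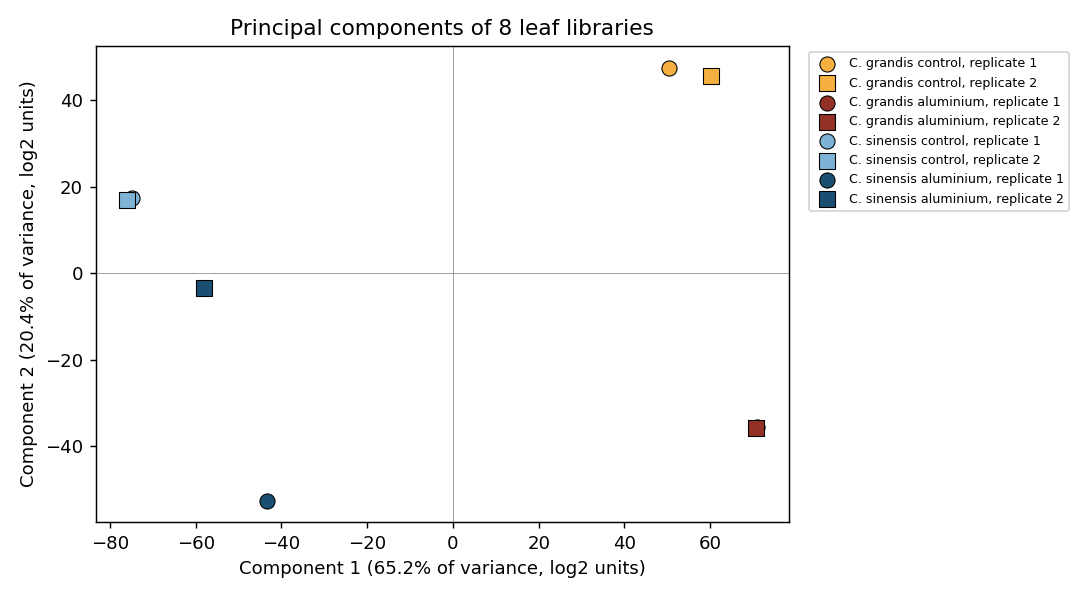
Principal components of log2(FPKM + 1) in the 8 libraries, with component 1 on the horizontal and component 2 on the vertical axis; colour gives the group and shape the replicate. Aluminium libraries lie below the control libraries of their species on component 2, with C. sinensis aluminium at -52.63 and -3.48.

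The first comparison asked which leaf transcripts of C. sinensis differed after 18 weeks of aluminium. Cs2g13910 rose from 6.74 ± 3.34 FPKM in control leaves to 352 ± 181 FPKM with aluminium (SD, n = 2 libraries), a log2 fold change of 5.48 (SE 0.43, limma adjusted p = 0.00948). In reads per library total this was 53.5-fold, with a 95% counting interval of 48.8 to 58.8. Cs7g06320 rose from 1.26 ± 0.077 to 66.2 ± 71.5 FPKM (SD, n = 2), a log2 fold change of 4.29 (SE 0.81, limma adjusted p = 0.0373), and its aluminium libraries stood at 117 and 15.6 FPKM. Cs9g03280 fell from 51.1 ± 23.3 to 1.8 ± 0.996 FPKM (SD, n = 2), by 4.19 on the log2 scale (SE 0.42, limma adjusted p = 0.00948). Cs8g19470 fell from 16.6 ± 13.4 to 0.205 ± 0.29 FPKM (SD, n = 2), by 3.64 on the log2 scale (SE 0.54, limma adjusted p = 0.0259). The 4 reads of Cs8g19470 left with aluminium, against 330 in control leaves, put its fold at 75.7 with a 95% counting interval of 29.3 to 280.

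With limma at an adjusted p below 0.05, 610 genes rose and 425 fell in C. sinensis, 6.3% of the 16327 tested. At least a 2-fold change was seen in 225 of those that rose and 111 of those that fell. Their median log2 fold changes were 0.83 and -0.81. In 60.8% of the genes tested both aluminium libraries lay on the same side of both control libraries, 6074 genes higher and 3852 lower. Independent genes with no effect would give 33.3%. Genes of a library can move together, and the scaling shifts them all, so the gap between these shares is no test of aluminium. The balance of rises and falls depended on the scaling: with libraries centred on their median, 316 genes rose and 788 fell, and after quantile normalization 317 rose and 536 fell. The median log2 change of all genes was 0.08 as deposited and -0.06 after centring. The number of calls depended on the libraries in the fit: limma on the 4 C. sinensis libraries alone, with 2 residual degrees of freedom in place of 4, called 0 genes, with 4068 at an unadjusted p below 0.05 where 816 are expected by chance, while voom on recovered reads of all libraries called 965. Calls numbered 58 with the C. grandis aluminium libraries counted as 1 or with either left out, 0 and 2 without C. sinensis control replicate 1 or 2, 2248 and 2250 without C. grandis control replicate 1 or 2, and 2163 without C. sinensis aluminium replicate 2.

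The second comparison asked the same of C. grandis. Cs1g16650 rose from 0.976 ± 0.485 FPKM in control leaves to 554 ± 5.85 FPKM with aluminium (SD, n = 2), a log2 fold change of 8.16 (SE 2.07, limma adjusted p = 0.0437). In reads per library total this was 555-fold, with a 95% counting interval of 381 to 843. Cs6g15360 had no read in either control library and 104 ± 0.225 FPKM with aluminium (SD, n = 2). This was at least 675-fold higher against a floor of 3 reads over the control group, and the log2 fold change was 6.72 (SE 1.78, limma adjusted p = 0.0482). Both calls were lost in 13 of 20 alternatives, and over all 20 the limma adjusted p ranged from 2.38e-05 to 0.21 for Cs1g16650 and from 1.59e-05 to 0.216 for Cs6g15360. In replicates 1 and 2 of C. sinensis aluminium, which also enter the shared spread, Cs1g16650 stood at 310 and 0.675 FPKM and Cs6g15360 at 96.1 and 0.0939 FPKM. Cs5g23760 fell from 16.7 ± 2.71 to 0.0352 ± 0.0498 FPKM (SD, n = 2), by 4.09 on the log2 scale (SE 0.17, limma adjusted p = 0.000227). It had 955 reads in control and 2 in aluminium leaves, a ratio of 462 with a 95% counting interval of 128 to 3820. Cs9g18210 fell from 27.8 ± 22.4 to 0.44 ± 0.108 FPKM (SD, n = 2), by 4.06 on the log2 scale (SE 0.51, limma adjusted p = 0.00546), and had no read in any of the 4 C. sinensis libraries. Cs2g13910 rose in this species too, from 37.2 ± 11.1 to 1410 ± 11.4 FPKM (SD, n = 2), a log2 fold change of 5.24 (limma adjusted p = 0.00177).

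In C. grandis, limma called 1046 genes that rose and 1584 that fell, 16.1% of the 16327 tested, of which 550 and 486 changed at least 2-fold. The median log2 fold change was 1.04 among the genes that rose and -0.76 among those that fell. Both aluminium libraries lay on the same side of both control libraries in 64.8% of the genes tested. Independent genes with no effect would give 33.3%, with the same limit as in C. sinensis. With libraries centred on their median, 1164 genes rose and 1190 fell, and 1046 and 1190 of these were also called without centring. The 4 C. grandis libraries alone gave 1093 rises and 1019 falls, of which only 714 and 830 were also called with all 8 libraries. With the C. grandis aluminium libraries counted as 1 replicate the calls dropped to 109 and 68, and without replicate 1 or 2 of that group to 235 and 194 in all. Calls numbered 1215 and 1217 without C. sinensis control replicate 1 or 2, and 4090 and 4095 without C. sinensis aluminium replicate 1 or 2.

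**Figure D2:**
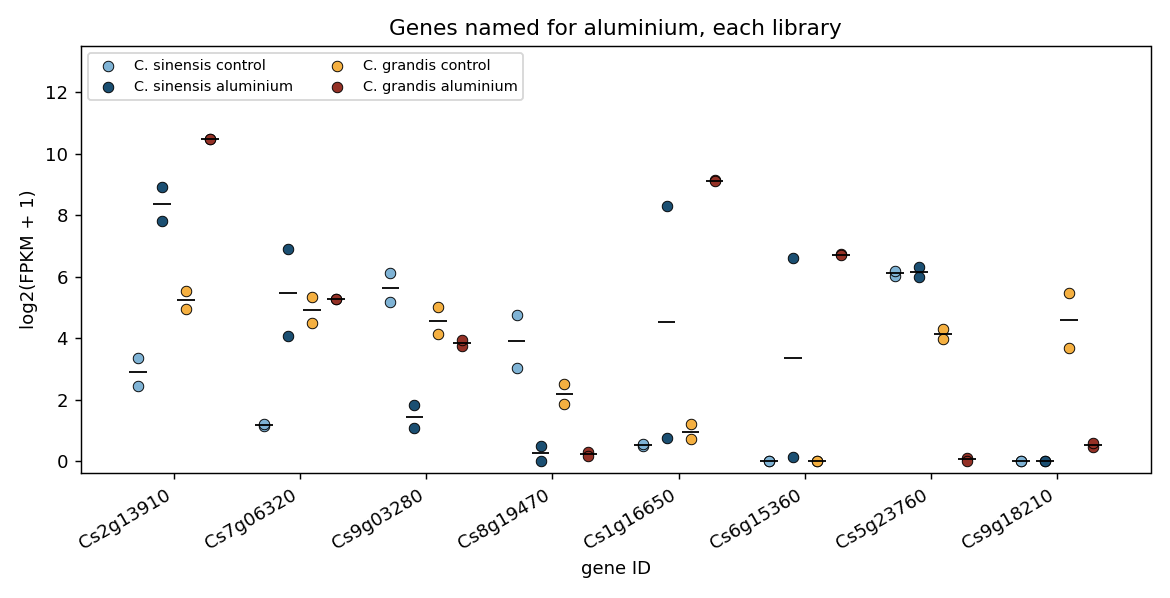
The vertical axis gives log2(FPKM + 1) of the 8 genes named for aluminium in either species, with a point per library, coloured by group, and a bar at the mean of 2 libraries. Cs1g16650 and Cs6g15360 are high in both C. grandis aluminium libraries and in 1 of the 2 C. sinensis aluminium libraries, at 310 and 96.1 FPKM.

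**Figure D3:**
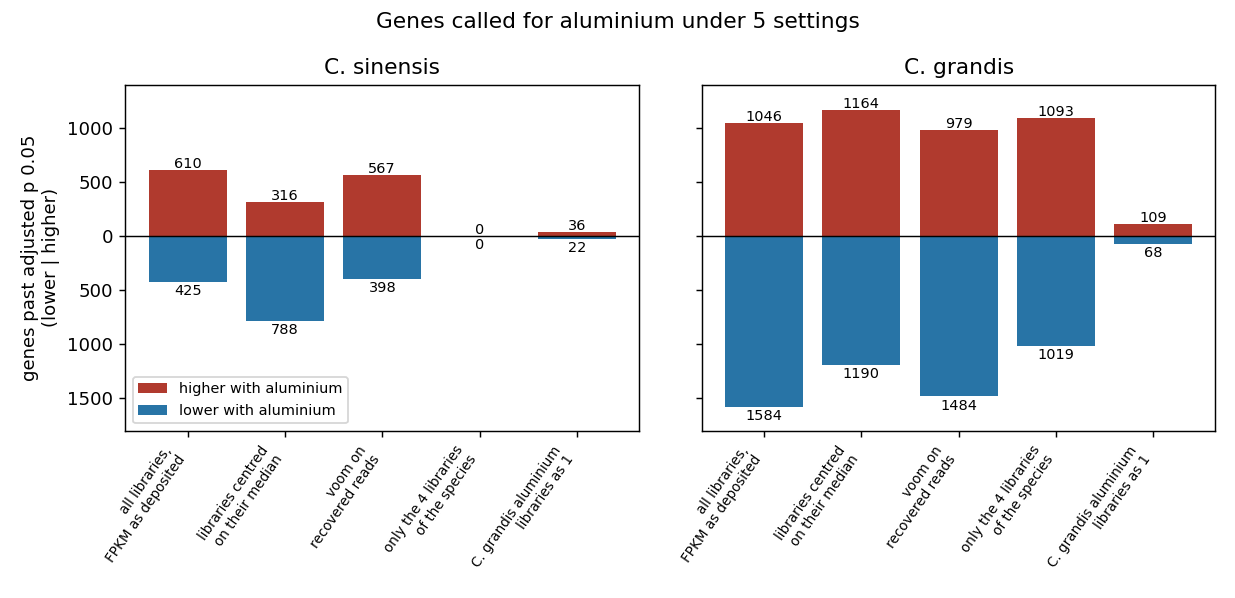
Number of genes called for aluminium (vertical axis, rises above 0 and falls below 0) in each species under 5 settings of the test. Counts as deposited were 610 and 425 in C. sinensis and 1046 and 1584 in C. grandis, and both dropped when the C. grandis aluminium libraries were counted as 1 replicate.

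The responses of the species overlapped. Of the genes tested, 202 rose in both species, where lists of these sizes drawn independently would share 39.1, and 221 fell in both, where 41.2 would be shared. Both tests use the same spread per gene, so genes of small spread can be called in both. Lists drawn independently within 50 bins of that spread would share 38.3 and 52.4. Opposite calls were fewer: 43 genes rose in C. sinensis and fell in C. grandis against 66.8 within bins of the spread, and 5 fell in C. sinensis and rose in C. grandis against 26.1. After median centring these opposite calls were 24 and 9, against 24.3 and 56 within bins. The 1046 genes that rose in C. grandis had a median log2 fold change of 0.45 in C. sinensis, and 85.3% of them had a positive one. The 1584 genes that fell in C. grandis had a median of -0.2 in C. sinensis, and 68.5% of them had a negative one. The median of all genes in C. sinensis was 0.08 as deposited, which favours positive signs. These shares therefore do not set rises against falls on equal terms. Across genes, which are not independent replicates, log2 fold changes of the species correlated with Pearson's r of 0.53 and Spearman's rho of 0.43. The r was 0.27 without C. sinensis aluminium replicate 1 and 0.59 without replicate 2. The 423 genes called the same way in both became 436 after median centring. They became 15 with the C. grandis aluminium libraries counted as 1, and 17 and 16 without replicate 1 or 2 of that group. They numbered 0 and 2 without C. sinensis control replicate 1 or 2, and 0 with each species fitted alone. Without C. grandis control replicate 1 or 2 they numbered 647 and 919, and without C. sinensis aluminium replicate 2 they numbered 1209.

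**Figure D4:**
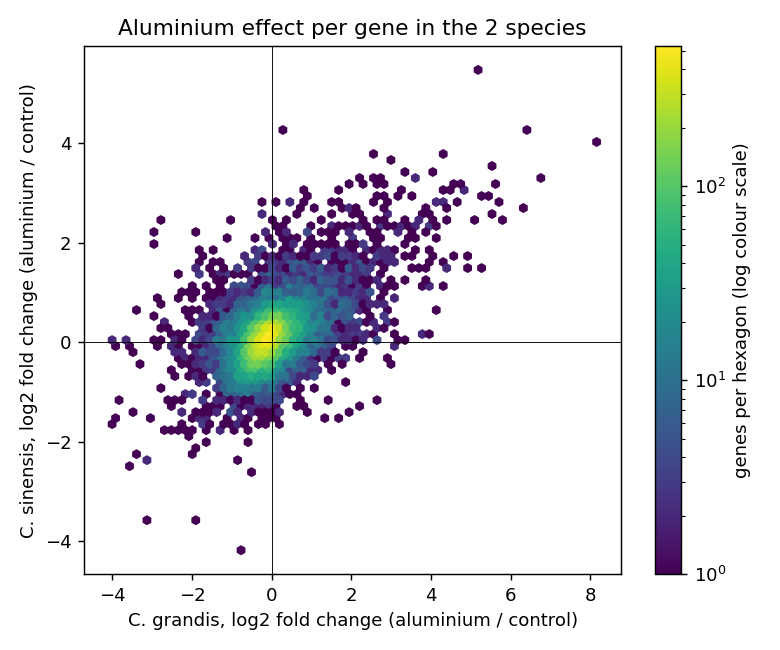
Log2 fold change with aluminium of 16327 genes in C. grandis (horizontal axis) and C. sinensis (vertical axis), with the number of genes per hexagon on a log colour scale. The cloud runs from lower left to upper right, with Pearson's r of 0.53 across genes.

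The difference of the aluminium effects between the species was tested directly. With aluminium Cs5g22210 rose from 0.778 ± 0.297 to 10.1 ± 7.66 FPKM in C. sinensis (SD, n = 2), while in C. grandis it fell from 5.83 ± 1.96 FPKM to no read. The latter was at least 127-fold lower against a floor of 3 reads over the group, and the log2 effects differed by 5.19 (SE 0.68, limma adjusted p = 0.022). Cs5g27570 rose in C. sinensis from 3.26 ± 0.864 to 17.6 ± 12.3 FPKM and fell in C. grandis from 296 ± 20.6 to 38.2 ± 0.00304 FPKM (SD, n = 2), with a difference of 4.89 (SE 0.6, limma adjusted p = 0.0192). Cs7g21790 rose in C. grandis from 0.141 ± 0.199 to 16.9 ± 1.33 FPKM (SD, n = 2) and had 6 reads in the C. sinensis aluminium libraries and none in its controls, with a difference of -3.85 (SE 0.25, limma adjusted p = 0.003). Cs1g23600 rose in C. grandis from 63.9 ± 23.7 to 403 ± 0.522 FPKM. In C. sinensis it stood at 441 ± 110 FPKM in control and 201 ± 50 FPKM in aluminium leaves (SD, n = 2, limma adjusted p = 0.0768). The effects of Cs1g23600 differed by -3.81 (SE 0.43, limma adjusted p = 0.0139).

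In all, limma called 378 genes whose aluminium effect differed, with the effect in C. sinensis above that in C. grandis for 248 and below it for 130. Of the 248, 200 were genes that fell in C. grandis, and 213 had effects of opposite sign, with median log2 fold changes of 0.46 in C. sinensis and -1.02 in C. grandis. Of the 130, 119 were genes that rose in C. grandis, with medians of 0.05 and 1.71, and 57 had effects of opposite sign. These shares rest on the same libraries as the test of the difference and are descriptive. The difference was called for 11.6% of the genes that rose and 12.6% of those that fell in C. grandis, and for 18.4% of the genes that rose and 4.5% of those that fell in C. sinensis. After median centring the split was 137 above and 209 below, and the median difference of all genes moved from 0.15 to -0.04. After quantile normalization the split was 143 above and 147 below. Calls numbered 242 with voom, 15 with the C. grandis aluminium libraries counted as 1, 20 and 16 without replicate 1 or 2 of that group, and 39 and 42 without C. sinensis control replicate 1 or 2. They numbered 1069 and 582 without C. grandis control replicate 1 or 2, and 1495 and 911 without C. sinensis aluminium replicate 1 or 2.

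The last comparisons set the species against each other within each treatment. In control leaves orange1.1t02091 stood at 252 ± 127 FPKM in C. grandis and 0.134 ± 0.135 FPKM in C. sinensis (SD, n = 2), a log2 difference of 7.71 (SE 0.32, limma adjusted p = 1.72e-05). For orange1.1t02040 the levels were 240 ± 158 and 0.538 ± 0.37 FPKM (SD, n = 2), a difference of 7.14 (SE 0.45, limma adjusted p = 6.8e-05). In the other direction, Cs9g06700 stood at 435 ± 39.5 FPKM in C. sinensis and 0.126 ± 0.0696 FPKM in C. grandis (SD, n = 2), a difference of -8.6 (SE 0.15, limma adjusted p = 1.93e-06). Cs9g06710, which follows it in the numbering, stood at 414 ± 32 and 0.734 ± 0.405 FPKM (SD, n = 2), a difference of -7.92 (SE 0.26, limma adjusted p = 1.02e-05). These 4 genes were also called in aluminium leaves, with log2 differences of 6.33, 5.83, -7.98 and -7.85. A set of 372 genes had at least 1 FPKM in all 4 C. sinensis libraries and fewer than 3 reads in each C. grandis library, while 78 genes showed the reverse. Reads of both species were counted on 1 gene set whose source is not given in the sources used here, so a missing gene and a gene whose reads were not placed look alike.

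Between control leaves limma called 4889 genes higher and 3090 lower in C. grandis, 48.9% of those tested, and between aluminium leaves 3099 higher and 3321 lower, 39.3% of those tested. After median centring the counts were 3300 and 3980 in control leaves and 3162 and 3265 in aluminium leaves. After quantile normalization they were 3680 and 3546 in control leaves and 3168 and 3172 in aluminium leaves. The excess of higher calls in control leaves thus turned with centring and shrank with quantile normalization. The median difference of all genes in control leaves was 0.17 as deposited and -0.01 after centring. Called in both treatments were 2376 genes higher in C. grandis and 2356 lower. These tests share their spread too, and lists independent within bins of it would have 964 and 657 genes in common. In opposite directions 73 genes were called. Across genes the log2 differences in control and aluminium leaves correlated with Pearson's r of 0.83 and Spearman's rho of 0.78. The median absolute log2 difference between species was 0.501 in control and 0.421 in aluminium leaves, and 0.466 and 0.419 after centring. Leaving out 1 library at a time gave 0.49 to 0.551 in control and 0.423 to 0.46 in aluminium leaves without centring, and 0.446 to 0.519 and 0.419 to 0.46 with it, so after centring the ranges overlapped. Calls in control leaves numbered 5101 and 4956 without C. sinensis control replicate 1 or 2. Calls in aluminium leaves numbered 3055 with the C. grandis aluminium libraries counted as 1, and 3036 and 3111 without replicate 1 or 2 of that group.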

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

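The tests of C. grandis RNA in a C. sinensis library, of 1 library read 2 times, of 1 RNA pool behind 2 libraries and of lost C. grandis reads were chosen after the results they bear on had been seen. The tests of gene length and of scaling had their predictions written before.

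The aluminium effect differed between the species for 378 genes by the limma test of the difference. Among the genes named in the report, the effect in C. sinensis minus that in C. grandis on the log2 scale was -3.45 for Cs9g03280 (limma adjusted p = 0.0448), 4.13 for Cs5g23760 (limma adjusted p = 0.003) and 4.06 for Cs9g18210 (limma adjusted p = 0.0462). The last of these had no read in C. sinensis in either treatment, so its difference restates its fall in C. grandis. The difference was 5.19 for Cs5g22210, 4.89 for Cs5g27570, -3.85 for Cs7g21790 and -3.81 for Cs1g23600. Cs5g23760 stood at 67.9 ± 6.06 FPKM in C. sinensis control and 70.2 ± 12 FPKM in C. sinensis aluminium leaves (SD, n = 2), while in C. grandis it dropped from 955 reads to 2.

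The aluminium libraries of C. sinensis differed in how near they lay to those of C. grandis, and Cs1g16650 and Cs6g15360 were high in replicate 1 alone. On the genes that rose in C. grandis, the median log2 change from the control mean, relative to the median change of all genes in that library, was 0.42 in replicate 1 and 0.24 in replicate 2, and on the genes that fell there it was -0.29 and -0.23. Cs1g16650 and Cs6g15360 stood at 310 and 96.1 FPKM in replicate 1, against means of 554 and 104 FPKM in C. grandis aluminium. RNA of C. grandis aluminium leaves could give these levels only as a large share of replicate 1. Yet 18 genes read in C. grandis and almost absent from C. sinensis control reached 0.284% of their C. grandis aluminium level in replicate 1. This argues against such RNA there. Replicate 2 reached 3.33%, with 3 or more reads on 1 of the 18 genes. A bias by gene length is argued against as well, since the correlation across genes between the library difference and the C. grandis response was 0.46 before and 0.46 after the mean of 20 length bins was removed. Pools of seedlings that had responded to different degrees, and handling or sequencing batches that the labels do not give, may account for the pattern and were not tested.

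The aluminium libraries of C. grandis differed far less than any other pair. 1 library sequenced again would give a mean chi-square per gene near 1 if its runs differed by counting error alone. The value was 1.77. A further run may add spread of its own that no pair here measures, so the value cannot decide. Libraries made from 1 pool of RNA cannot be told apart from separate, very similar pools: the spread beyond counting error was 0.023 on the log2 scale against 0.095 in the closest other pair, and no pair known to be technical gives the spread of library preparation alone. The labels describe separate pools, and seedlings that converge after 18 weeks of aluminium remain an untested possibility. With that pair as 1 replicate the calls for aluminium in C. sinensis numbered 58 and those in C. grandis 177.

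In control leaves 61.3% of the calls between species were higher in C. grandis, and in aluminium leaves 48.3%, while after centring libraries on their median the shares were 45.3% and 49.2%. Scaling by the library total cannot be told apart from a true difference, because centring itself brings the median difference to about 0 and so sets the balance of calls. Loss of C. grandis reads on a gene set of another species would bear on the same genes in both treatments, so alone it would not give a gap between them. Such loss cannot be judged from the gap of 13.0 percentage points, which restates the pattern and does not hold after centring. The C. sinensis control libraries gave 22.6% and 23.1% of their reads to their 100 most abundant genes, against 15.3% and 16.4% in C. grandis control. Total RNA per cell, which would bear on a true difference, was not analysed here.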

How the results depend on the processing

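The 16 results for named genes kept their direction in each of 314 alternative fits and passed the threshold in 241 of them. The 4 genes named for the species in control leaves and Cs5g23760 passed in all 20 alternatives each, while Cs1g16650 and Cs6g15360 passed in 7 of 20, Cs7g06320 in 10 of 20, Cs8g19470 in 11 of 20 and Cs5g22210 in 11 of 18. The kept direction is no evidence of its own. The naming rule took the largest changes with separated libraries, and leaving out a library or changing the pseudocount or prior cannot turn those. Counts of calls moved more than these results. Genes called for aluminium in C. sinensis (1035) became 654 without a filter on low values and 0 with only the libraries compared. Calls for the difference (378) became 240 with a filter at 5 FPKM and 242 with voom on recovered reads. Genes called the same way in both species (423) became 260 without the filter and 0 with only the libraries compared. With the C. grandis aluminium libraries as 1 replicate, an alternative chosen after seeing the data like voom, the counts were 58 for aluminium in C. sinensis, 177 for aluminium in C. grandis (2630), 15 for the difference, 3055 for the species in aluminium leaves (6420) and 15 for the overlap. By construction that setting drops the pair with the smallest spread and 1 residual degree of freedom; the cause of the other shifts was not tested.

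Leaving out 1 library at a time gave 0 to 2250 calls for aluminium in C. sinensis, 194 to 4095 for aluminium in C. grandis, 16 to 1495 for the difference, 4956 to 9001 for the species in control leaves (7979), 3036 to 7696 for the species in aluminium leaves and 0 to 1209 for the overlap. The lone library left in a group is then assumed to vary like the other groups. Counts were lower without a library of C. grandis aluminium or C. sinensis control, the closest pairs, than without one of the other groups in each of these 6 results.

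With the replicate block, the counts were 1 for aluminium in C. sinensis, 1289 for aluminium in C. grandis, 36 for the difference, 4819 for the species in control leaves, 3205 for the species in aluminium leaves and 1 for the overlap. The difference between replicates 1 and 2 of a group correlated across genes with that of another group by -0.01 to 0.05. Between the control and aluminium groups of a species, within which the block was fitted, it was 0.02 in C. grandis and 0.05 in C. sinensis. No effect shared by same-numbered libraries was thus seen. The C. grandis aluminium pair differed by little more than counting error, so the value for C. grandis could hardly show such an effect. The replicate block left 2 residual degrees of freedom. The pseudocounts, the scalings, the priors and the fold minimum kept these counts within 1.5 times, though the scalings moved the split of rises and falls. The genes called changed more than the counts. Median centring kept 741 of the 1035 calls for aluminium in C. sinensis, 2236 of the 2630 in C. grandis and 267 of the 378 for the difference. Tests that need deposited counts and the tests of gene lists were not run, since the files hold FPKM and IDs without names. Depth limits low genes: 3 reads at the median gene length equal 0.0936 to 0.113 FPKM.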

Other observations

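The tests of the ID series and the counts of genes read in 1 species were chosen after seeing the data. The prediction for neighbouring genes was written before its result was seen.

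Genes next to each other in the ID numbering were called the same way for aluminium in more pairs than shuffled calls gave, though in a small part of all pairs. Among 8861 pairs of neighbouring tested genes in the numbered series, 196 pairs were called the same way in C. grandis, against a mean of 128.2 over 2000 shuffles of the calls within each series (permutation p = 0.0005, the smallest the shuffles can give), a ratio of 1.53. In C. sinensis 27 pairs were called the same way against 19.4 (permutation p = 0.0455), and after median centring 42 against 25.3 (permutation p = 0.0025). The shuffles move calls between genes, so these p-values do not measure variation between pools of leaves. The hypothesis that responding genes lie together, as copies of a gene family in tandem or under shared control may do, is consistent with these counts. Reads shared between similar neighbours or overlapping gene models would give the same excess and were not tested, since the sequences were not used here. The difference between species in control leaves showed the excess too, with 1373 pairs against 1148.7 (permutation p = 0.0005), and Cs9g06700 and Cs9g06710 form such a pair.

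The share of aluminium calls was also compared between the ID groups (the numbered series, orange1.1t and the remaining IDs), in both directions and both species. With FPKM as deposited, 0 of 44 Fisher's exact tests over genes passed the threshold after adjustment. After median centring 1 of 44 did: in Cs3g, 9.2% of 1637 genes rose in C. grandis against 6.9% of the other genes (Fisher's exact test, adjusted p = 0.0357), where without centring the shares were 8.2% and 6.2% (adjusted p = 0.0969).

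Of the 372 genes read in C. sinensis and nearly absent from C. grandis, 88 carry IDs outside the numbered and orange1.1t series, as do 416 of the 14924 genes with at least 1 FPKM in all 4 C. sinensis libraries. Of the 78 genes with the reverse pattern 32 carry such IDs, as do 331 of the 14497 genes with at least 1 FPKM in all 4 C. grandis libraries. How these IDs were defined is not given in the sources used here. The shares therefore cannot separate a difference between the species from the way the IDs were made. The median level of these sets in their own species was 4.12 and 4.19 FPKM.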
